A study of Homo sapiens with 5 samples.

How the data were processed

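The series holds 5 RNA-seq libraries of C4-2B cells, an established castration-resistant human prostate cancer line derived from LNCaP. Per the labels, RNA was extracted with Trizol and libraries were made with the Illumina TruSeq RNA kit. The treatments were YDGY-3 at 20 nM, YDGY-3BR at 20 nM and IPZ, an abbreviation the labels do not spell out, with a dose the labels write as 20 mM. Exposure to these compounds was 24 h, and none is given for vehicle. The unit prefix of the IPZ dose could not be checked against the data, so it is given only as the labels have it. DMSO vehicle was sequenced in 2 libraries, called vehicle 1 and vehicle 2 after their labels.

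The values come in 2 tables that were deposited separately. The first holds vehicle 1 and YDGY-3, the second vehicle 2, IPZ and YDGY-3BR. Per the file headers, both tables give FPKM (fragment counts scaled by gene length and library depth) computed by the authors, and the second also gives read counts. The deposited read counts are estimated counts, since 55.0% of the values in vehicle 2 are whole numbers and the others carry decimals. Bowtie 0.12.2 and the builds mm8 and GRCh38.p12 are named in the submitters' processing notes with no role for any of them. As mm8 is a mouse build and the cells are human, its role is left open. The gene counter, annotation and filters are not given in the sources used here. The second table also has 3 columns of TPM, which were not used. The tables list 18003 and 18054 genes by Entrez ID, with 17331 IDs in both. Symbols were taken from the second table. Of the 672 IDs found only in the first table, 567 were named from the RefSeq gene table of assembly GRCh38.p14, used for names only.

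The estimated counts summed to 19487538 in vehicle 2, 19469290 in YDGY-3BR and 19345260 in IPZ. The first table gives no counts. Its depth relative to vehicle 2 was estimated from low genes whose FPKM moves in steps of whole reads. This gave 0.988 for vehicle 1 (43 genes, 74.4% within 0.1 read of a whole number) and 0.974 for YDGY-3 (34 genes, 64.7% within 0.1 read). The same procedure gave 1.0 for IPZ and 0.995 for YDGY-3BR, where the counts and FPKM give 0.993 and 0.999. The shares are too low to recover reads per gene, so no intervals are given for the first table. For the second table, 95% intervals of a ratio were computed from the rounded estimated counts and the count totals by the exact binomial (Clopper-Pearson) method. Intervals and floors cover counting error only. A gene at 0 counts was set at a floor of 3 counts in that library to give a bound of its fold.

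Each treated group has 1 library, so no test, p-value or standard error was computed. Differences are of log2(FPKM + 1), with a pseudocount of 1, which understates the change of low genes. Folds quoted in words are ratios of FPKM. A gene passed the size rule if its FPKM was at least 1 in the higher library and its difference was at least 1 in either direction. Each compound was compared with the vehicle of its own table, and IPZ with YDGY-3BR inside the second table. The tables were normalized separately, so values set across them carry that limit. Differences of YDGY-3 and YDGY-3BR were compared by Pearson correlation across genes with a mean FPKM of at least 1, and by overlap of genes past the size rule beside the overlap of independent lists. IPZ and YDGY-3BR share vehicle 2. Their correlation and covariance were therefore set beside 100 simulations of unchanged libraries against a shared control, with the spread taken from the 2 vehicle libraries. These lie in different tables, and the simulated correlation is fixed near 0.5 by construction, so only the covariance can serve for comparison.

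The comparisons, the size rule, the alternatives, the naming rule and 35 gene lists were chosen before the data were examined. Each list's median difference was placed among the medians of 10000 random lists of equal size, matched on mean expression in 20 bins and drawn with replacement within a bin. Its percentile is a description of these libraries. A member counted as measured in a comparison if its FPKM was at least 1 in the higher of the 2 libraries. A gene low in vehicle therefore entered only where the compound raised it. The denominators differ between comparisons, and shares and medians of lists low in vehicle are not directly comparable between compounds. The lists of mitochondrially encoded genes and nuclear long noncoding RNAs had 0 members in the tables. Named genes were taken from the 10 largest differences each way for each compound and the 5 largest each way for IPZ against YDGY-3BR. These had an FPKM of at least 5 in the higher library, and small RNAs, clones, unnamed loci and pseudogenes were left out. From each list the text names members with the largest absolute differences. KPNB1, MYC and KLK3 were followed in every comparison. Multi-copy genes such as SSX2B, GAGE1, PRSS1, TUBA3D, HBA1 and HBA2 are uncertain, because reads can be split among near-identical copies.

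Alternatives were a pseudocount of 0.1, no filter on low values, an FPKM of at least 5, differences centred on their median, a size rule of 2, and the vehicle of the other table. Trimmed mean of M values (TMM) factors from edgeR 4.0.16, computed on the rounded estimated counts, were added after the data were seen. The counting of genes was tested on simulated libraries drawn from vehicle 2 with Poisson noise. It recovered 50 of 50 genes at each of the folds 4, 3, 0.333 and 0.25, and put 0 of 11396 unchanged genes past the size rule. The changed genes had an FPKM of at least 5 in vehicle 2, and the simulated noise was counting error only. Between the 2 real vehicle libraries 291 genes (2.51%) passed, so the test checks the procedure and gives no rate of false calls for these data. Of 100 unchanged lists of 30 genes, 5 lay outside the central 95% of matched random lists. Those lists were random genes under counting error only, so this share does not carry over to the gene lists in real libraries. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3. Coordinates of genes are from GENCODE release 29 on GRCh38, since the tables carry none.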

Results

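The transcriptomes of C4-2B prostate cancer cells were profiled after 24 h with IPZ or with either YDGY-3BR or YDGY-3 at 20 nM, and in DMSO vehicle, for which the labels give no exposure time. The series title describes daphnane diterpenoids as inhibitors of importin-β1, the nuclear import receptor encoded by KPNB1, in castration-resistant prostate cancer. Each compound has 1 library and vehicle has 2, so there are no replicates of a treatment and no difference below has a replicate check. From 11173 to 11677 genes per library reached an FPKM of 1. The estimated read counts summed to 19487538 in vehicle 2, 19469290 in YDGY-3BR and 19345260 in IPZ, and the table of vehicle 1 and YDGY-3 gives no counts.

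KLK3, which encodes prostate-specific antigen and is known to be induced by androgen, was lower in all 3 treated libraries than in vehicle. Its FPKM was 1013 in vehicle 1 and 182 with YDGY-3, a 5.57-fold lower level. It was 1164 in vehicle 2, 60.6 with YDGY-3BR (19.2-fold lower) and 402 with IPZ (2.89-fold lower). From the counts, YDGY-3BR stood at 0.0507 to 0.0557 of vehicle 2 and IPZ at 0.335 to 0.350 of it (95% intervals). KLK3 (Entrez ID 354) lies on chromosome 19 from 50854915 to 50860764 in GRCh38.

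MYC (ID 4609, chromosome 8, 127735434 to 127741434), a growth-promoting transcription factor, had an FPKM of 117 in vehicle 1 and 36.9 with YDGY-3. The values were 58.0 in vehicle 2, 10.4 with YDGY-3BR and 45.0 with IPZ. Its difference was -1.64 for YDGY-3, -2.37 for YDGY-3BR and -0.36 for IPZ. The vehicles themselves differed in MYC, and against the vehicle of the other table these differences became -0.64, -3.37 and -1.36. KPNB1 (ID 3837, chromosome 17, 47649476 to 47685505) did not pass the size rule in any comparison. Its FPKM was 131 in vehicle 1 and 102 with YDGY-3, and 162 in vehicle 2, 111 with YDGY-3BR and 106 with IPZ. All 3 genes lie on the plus strand and are protein-coding.

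**Figure D1:**
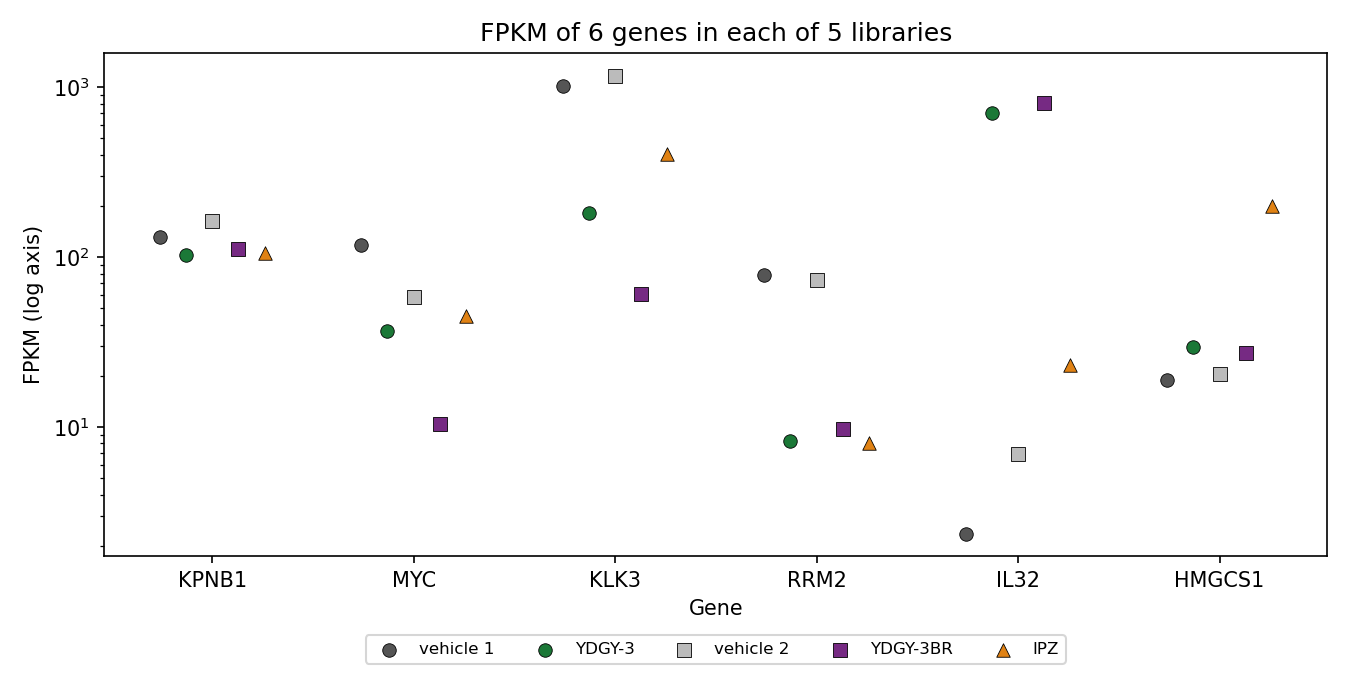
FPKM (log axis) of 6 genes in each of the 5 libraries, 1 point per library with no error bars because each point is 1 library. KLK3 was lower in each treated library than in its vehicle, IL32 was far higher with YDGY-3 (708) and YDGY-3BR (806), and HMGCS1 was highest with IPZ (199).

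YDGY-3 was compared with vehicle 1 to ask which transcripts differ after exposure to this compound. IL32, a cytokine gene, stood at 2.36 FPKM in vehicle 1 and 708 with YDGY-3 (difference 7.72). CRYAB, a small heat shock protein gene, went from 2.80 to 420 (6.79), and the keratin gene KRT75 from 0.99 to 195 (6.62). DIO3, which encodes a thyroid hormone deiodinase, differed by 6.50. TCIM (5.48), RARRES3 (5.45), S100P (5.24), CSF1 (5.23), GDF15 (5.20) and TMSB4X (5.12) completed the 10 largest. GDF15 encodes a stress-responsive cytokine and CSF1 the macrophage colony-stimulating factor. On the lower side, the peptide hormone gene APLN differed by -3.50, and the mitotic kinase gene AURKB by -3.29, from 71.6 to 6.44 FPKM. RRM2, a subunit gene of ribonucleotide reductase, differed by -3.10. UHRF1 (-2.96), ASF1B (-2.91), CDKN2C (-2.91), KLK2 (-2.83) and CDC45 (-2.83) followed. SSX2B (-2.91) belongs to a family of near-identical copies, and it stood at 9.04 FPKM in vehicle 1 but 0.25 in vehicle 2.

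Among 11897 genes compared, 1020 were higher and 726 lower with YDGY-3 past the size rule. All but 1 of the 42 measured G1/S and DNA replication genes were lower past the rule and 0 higher (median -2.05, percentile 0), among them E2F1 (65.5 to 8.59 FPKM). In the G2/M and mitosis list 43 of 45 were lower (median -1.80), including CDC20 (-2.59) and PLK1 (-2.59). DNA repair and homologous recombination genes were lower past the rule in 22 of 31 cases, led by RAD54L (-2.45) and EXO1 (-2.42). Of 39 MYC targets, 14 were lower (median -0.84), with BOP1 (-1.74) and LYAR (-1.67) lowest. Androgen-induced genes split, with 10 of 33 lower and 3 higher (median -0.25, percentile 2.1). Here ALDH1A3 was higher (3.55), and KLK2 and KLK3 were among the lowest. Among importin and nuclear transport genes, 4 of 32 were lower and 1 higher (median -0.37, percentile 0.33). RANBP1, a Ran-binding protein gene, stood at -1.53 and IPO4 at -1.22. KPNA7 was listed at 0 in vehicle 1 and stood at 2.02 FPKM with YDGY-3. Nucleoporin genes were lower in 7 of 31 cases (median -0.49), with NUP210 at -1.37 and NUP93 at -1.30.

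NF-kB targets were higher with YDGY-3 in 16 of 21 measured cases and lower in 0 (median 1.80, percentile 100). BIRC3 went from 0.18 to 26.2 FPKM, TNF from 0.09 to 19.5 and RELB from 0.87 to 24.0. Interferon-stimulated genes were higher in 21 of 33 cases (median 1.33, or 2.18 with a pseudocount of 0.1), with IFI27 at 5.11 and OASL at 3.97. AP-1 and immediate early genes were higher in 18 of 32 cases and lower in 1 (percentile 100), with DUSP5 at 4.33 and ATF3 at 3.85. TGF-beta and YAP targets were higher in 10 of 18 cases, including CYR61 (2.60) and ID2 (2.23). In the NRF2 oxidative stress list 13 of 25 were higher and 1 lower (median 1.06). AKR1C1 differed by 4.58, SQSTM1 by 3.57, from 155 to 1848 FPKM, and HMOX1 by 3.25. ATF4 target genes were higher in 6 of 35 cases and lower in 2 (median 0.27). Cholesterol biosynthesis genes were higher in 1 of 25 cases and lower in 2 (median -0.25, percentile 5.51), and fatty acid synthesis genes were lower in 2 of 17 (median -0.50, percentile 0.29). Of leukocyte markers, 4 of 16 found in the tables reached 1 FPKM, and CD68 (3.39 to 94.1 FPKM) and ITGAM (0.03 to 2.34) were higher past the rule. PTPRC, the pan-leukocyte gene CD45, stood at 0.18 in vehicle 1 and 0.41 with YDGY-3. Several of these genes are near 0 in vehicle 1, where no counts are given, so the size of their difference rests on few reads.

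YDGY-3BR was compared with vehicle 2 in the same way. CRYAB was listed at 0.97 FPKM in vehicle 2 and 1963 with YDGY-3BR, a 2024-fold ratio with a counting interval of 1087 to 2987. KRT75 (0.10 to 550 FPKM, 4 reads in vehicle 2) and DIO3 (0.27 to 561, 11 reads) were next. UBD, a ubiquitin-like modifier gene, had 3 reads in vehicle 2 and 3483 with YDGY-3BR, a 1152-fold ratio with a counting interval of 397 to 5638. CSF1 (6.94), TNF (6.82), IL32 (6.68), DUSP5 (6.53) and MUC20 (6.53) followed. MMP12, a matrix metalloproteinase gene, had 1 read in vehicle 2 and 3057 with YDGY-3BR, with a counting interval of the ratio from 549 to 120897. On the lower side were KLK2 (-4.29), KLK3 (-4.24), AADAT (-3.88), APLN (-3.69), CBLN2 (-3.56) and the phospholipid phosphatase gene PLPP1 (-3.55). TUBA3D (-3.34), METTL7A (-3.21) and MCCC2 (-3.20), the last an enzyme of leucine breakdown, followed.

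Of 12159 genes, 1297 were higher and 1352 lower with YDGY-3BR past the size rule. The median gene with a mean FPKM of at least 5 differed by -0.13, and with differences centred on that shift the counts were 1518 higher and 1044 lower. The higher share moved from 49.0% to 59.3%. G1/S and DNA replication genes were lower in 41 of 42 cases (median -1.96), with UHRF1 at -3.11 and CCNE2 at -2.71. G2/M and mitosis genes were lower in 43 of 45 cases (median -1.62), with KIF20A at -2.65 and AURKB at -2.57. DNA repair genes were lower in 24 of 31 cases (median -1.49), with RAD54L at -2.23. In the MYC target list 21 of 39 were lower (median -1.04), with BOP1 at -2.13 and CAD at -1.95. Androgen-induced genes were lower in 19 of 34 cases and higher in 4 (median -1.12, percentile 0). KLK2, KLK3 and ALDH1A3 (3.64, higher) had some of the largest absolute differences. Importin and transport genes were lower in 6 of 32 cases and higher in 1 (median -0.55, percentile 0.1). RANBP1 stood at -2.02, IPO4 at -1.55, IPO5 at -1.44 and KPNA7 at 2.84. Nucleoporin genes were lower in 7 of 31 cases (median -0.52), with NUP35 at -1.52. Importin and nucleoporin genes were also higher in vehicle 2, the reference here, than in vehicle 1, by medians of 0.24 and 0.29.

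NF-kB targets were higher in 21 of 24 measured cases and lower in 0 (median 2.15). TNF went from 0.37 to 154 FPKM, CCL2 from 0.99 to 112 and TRAF1 from 0.08 to 48.5. Interferon-stimulated genes were higher in 25 of 35 cases (median 1.51), led by IFI27 (5.07), RSAD2 (4.78) and OASL (4.73). AP-1 and immediate early genes were higher in 20 of 33 cases and lower in 1, which was MYC (median 1.25). PLAU, the urokinase gene, had 0 reads in vehicle 2 and was at least 756-fold higher against the floor of 3 counts. TGF-beta and YAP targets were higher in 14 of 20 cases, with CDKN2B at 3.45 and CYR61 at 3.21. NRF2 oxidative stress genes were higher in 13 of 25 cases and lower in 1, with HMOX1 at 4.97, AKR1C1 at 4.87, SQSTM1 at 4.19 and FTL at 3.10. ATF4 target genes were higher in 12 of 35 cases and lower in 3 (median 0.27), with ATF3 (4.55), PPP1R15A (3.14) and CHAC1 (2.85) highest. Cholesterol biosynthesis genes were lower in 1 of 25 cases and higher in 0 (median -0.25, percentile 24.4). Fatty acid synthesis genes were lower in 5 of 16 (median -0.79), with ACACA at -1.75 and ELOVL5 at -1.47. Of the leukocyte markers, 7 of 16 reached 1 FPKM, and CD68 (5.15 to 231 FPKM), ITGAM (0.05 to 4.54) and CSF1R (0.04 to 2.17) were higher. PTPRC stood at 0.26 in vehicle 2 and 0.15 with YDGY-3BR.

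YDGY-3 and YDGY-3BR were given at the same dose and time, and their differences from their own vehicles were compared gene by gene. Past the size rule, 847 genes were higher in both and 669 lower in both, against 99.9 and 82.1 for independent lists, and 0 went opposite ways among 11655 genes compared in both. Across 11653 genes the correlation of differences was 0.915 (Pearson, across genes, which are not independent replicates), and 83.1% had the same sign. The principal-axis slope of YDGY-3BR on YDGY-3 was 1.25. Differences were greater with YDGY-3BR for CRYAB (by 3.17), TNF (by 2.59), KRT75 (by 2.35) and DUSP5 (by 2.20). KLK3 differed between the compounds by -1.77 and MYC by -0.73. IL32 went the other way, at -1.05, with a level of 708 FPKM for YDGY-3 and 806 for YDGY-3BR. RRM2 (0.30) and KPNB1 (-0.18) differed by less than the size rule. In all, the signed difference was higher with YDGY-3BR than with YDGY-3 by at least 1 for 159 genes, and lower by at least 1 for 180. The 180 include genes such as KLK3 that fell further with YDGY-3BR. Between the vehicles 282 of the 11653 genes differed by at least 1 in either direction, with no compound in either library. Over these genes the robust SD, scaled from the median absolute deviation, was 0.301 for the difference between compounds and 0.422 between vehicles. A shift between tables enters the vehicle comparison but can cancel in the difference between compounds, so the 282 are no direct background for the 159 and 180. The compounds lie in separately normalized tables, with 1 library each, and no interval of their difference can be given.

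**Figure D2:**
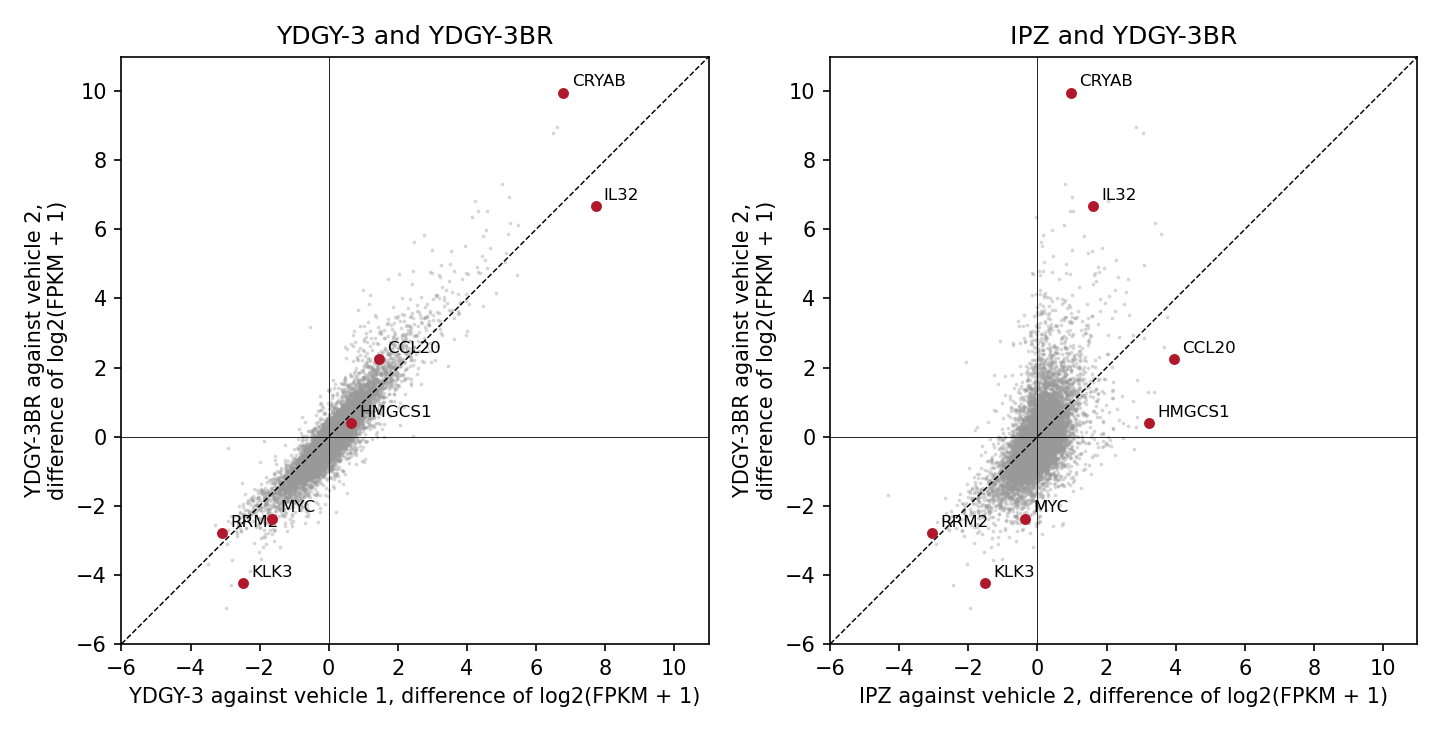
Differences of log2(FPKM + 1) for YDGY-3BR against vehicle 2 (vertical axes) set against YDGY-3 against vehicle 1 (left) and IPZ against vehicle 2 (right), 1 grey point per gene with a mean FPKM of at least 1, 7 genes labelled in red, and a dashed line of equality. Points on the left follow the diagonal (r 0.915), while on the right HMGCS1 and CCL20 lie to the IPZ side and CRYAB and IL32 to the YDGY-3BR side (r 0.573).

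IPZ was compared with vehicle 2. The chemokine gene CCL20 was highest, at 1.82 FPKM in vehicle 2 and 42.4 with IPZ (difference 3.94). LCN2, a secreted lipocalin gene, differed by 3.76, GPNMB by 3.67, GDF15 by 3.58, S100P by 3.40 and the trypsinogen gene PRSS1 by 3.37. HMGCS1, the synthase that starts the mevalonate route, stood at 20.6 in vehicle 2 and 199 with IPZ. That is a 9.69-fold ratio with a counting interval of 9.38 to 10.4. DDIT4 (3.21), the heme oxygenase gene HMOX1 (3.09) and CHAC1 (3.08), which degrades glutathione, completed the higher side. On the lower side were RRM2 (73.3 to 8.01 FPKM), UHRF1 (-2.94), MCM10 (-2.92), FAM111B (-2.74), MCM5 (-2.68), MCM4 (-2.66), DTL (-2.62), E2F1 (-2.57) and ASF1B (-2.55), most of them known for roles in DNA replication. GAGE1 (-4.34) belongs to a multi-copy family and stood at 134 FPKM in vehicle 1 but 24.1 in vehicle 2, and its FPKM ratio (100-fold lower) lies outside the 95% interval of its counts, 0.0320 to 0.102 of vehicle 2. LCN2 also differed between vehicles, at 0.06 and 4.86 FPKM.

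Of 11878 genes, 365 were higher and 401 lower with IPZ past the size rule. Cholesterol biosynthesis genes stood out on the higher side, with 19 of 25 higher and 0 lower (median 1.58, percentile 100). INSIG1 differed by 2.84, MSMO1 by 2.80 and SQLE by 2.14. Fatty acid synthesis genes were higher in 4 of 18 cases (median 0.64), with ACSL1 at 2.49 and ACSS2 at 2.10. ATF4 target genes were higher in 24 of 35 cases and lower in 0 (median 1.47). DDIT4 went from 41.6 to 393 FPKM, and DDIT3, the pro-apoptotic factor CHOP, differed by 2.89. NRF2 genes were higher in 13 of 24 cases (median 1.08), with MT1F at 2.63 and SQSTM1 at 2.56. NF-kB targets were higher in 9 of 22 cases (median 0.91), with BIRC3 at 2.27. AP-1 genes were higher in 4 of 25 (median 0.35), interferon-stimulated genes in 2 of 28 with 1 lower (median 0.25), and TGF-beta and YAP targets in 3 of 17. Leukocyte markers were past the rule in 0 of 7 cases.

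G1/S and DNA replication genes were lower in 40 of 42 cases with IPZ (percentile 0), and G2/M genes in 27 of 45 (median -1.09), with MYBL2 at -2.02 and AURKB at -1.93. DNA repair genes were lower in 20 of 31 cases, with EXO1 at -2.46, and MYC targets in 8 of 39 (median -0.62), with LDHA at -1.23. Androgen-induced genes were lower in 11 of 32 cases and higher in 2 (median -0.58), with KLK2 at -2.45 and FKBP5 at -1.73. Importin and transport genes were lower in 2 of 31 cases (median -0.43), with RANBP1 at -1.49 and CSE1L at -1.16. Nucleoporin genes were lower in 6 of 31 (median -0.57), with NUP205 at -1.27. Beside these 2 medians stand those of vehicle 2 against vehicle 1, 0.24 for importin and 0.29 for nucleoporin genes. Against vehicle 1 the IPZ counts were 927 higher and 724 lower, and with a pseudocount of 0.1 against vehicle 2 the higher count was 611, so the size of the IPZ count depends on these choices.

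**Figure D3:**
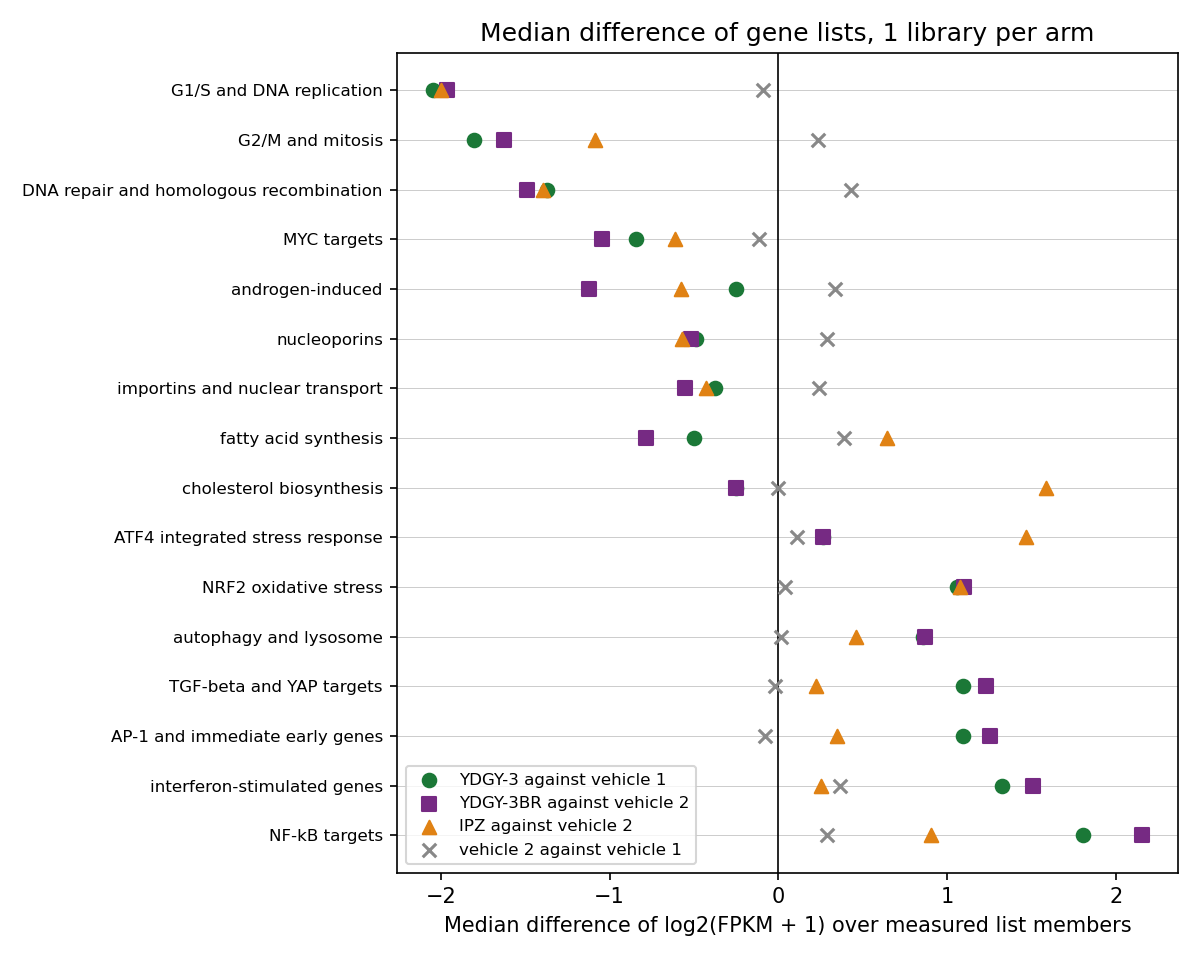
Median difference of log2(FPKM + 1) over the measured members of 16 gene lists (horizontal axis) for each compound against the vehicle of its table, with vehicle 2 against vehicle 1 as crosses. Each point is a comparison of 1 library with 1 library, without error bars. Replication genes lie near -2.0 for all 3 compounds, and cholesterol biosynthesis (1.58) and ATF4 genes (1.47) lie higher for IPZ than for the other compounds.

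IPZ and YDGY-3BR were compared directly inside the second table. CLGN, a testis chaperone gene, was higher with IPZ (3.25), as were the metallothionein gene MT1X (3.23), the sterol enzyme gene MSMO1 (3.16), METTL7A (3.07) and the prostaglandin receptor gene PTGFR (3.04). CRYAB was lower with IPZ (-9.00), as were UBD (-6.53), KRT75 (-6.13) and CSF1 (-5.96). MMP12 had 0 reads with IPZ and was at least 1013-fold lower against the floor of 3 counts. MYC (2.02) and KLK3 (2.71) were higher with IPZ past the size rule, while KPNB1 (-0.07) was not. Of 12203 genes, 819 were higher and 938 lower, and 645 and 1051 with centred differences, which took the higher share from 46.6% to 38.0%. Cholesterol genes were higher with IPZ in 20 of 25 cases, fatty acid genes in 12 of 18, with SCD at 2.62, and ATF4 genes in 20 of 35 with 2 lower, with PHGDH at 2.34. NF-kB targets were lower with IPZ in 16 of 24 cases and higher in 1. Interferon-stimulated genes were lower in 21 of 35 and AP-1 genes in 19 of 33, with OASL at -4.89 and DUSP5 at -5.59. For G1/S genes 0 of 42 passed the rule either way (median 0.00), and G2/M genes were higher with IPZ in 4 of 45 (median 0.66), with PTTG1 at 1.26.

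Against vehicle 2, 201 genes were higher and 330 lower with both IPZ and YDGY-3BR, where independent lists give 29.2 and 46.4, and 12 genes went opposite ways. The correlation of differences was 0.573 and their covariance 0.302. Unchanged libraries simulated against a shared control gave a correlation of 0.5 (0.487 to 0.514 over 100 runs). They gave a covariance of 0.0775 and 20.1 genes past the rule in both. The simulated correlation follows from giving each simulated library the same spread for a gene, whatever the data. It therefore does not measure how much of the observed 0.573 is due to the shared vehicle. The observed covariance exceeded the simulated one by 0.224. With vehicle 1 as the control of IPZ, so that no control was shared, the correlation was 0.423. This sets IPZ against a vehicle of the separately normalized first table, so the lower value cannot be assigned to the shared vehicle alone. The simulated covariance already includes a shared control, with its spread taken from the 2 vehicle libraries. Those libraries lie in different tables, while IPZ, YDGY-3BR and vehicle 2 share 1 table. The spread includes any shift between tables, so the simulated covariance and the 20.1 genes may be too high for libraries of 1 table. For YDGY-3 and IPZ, which share no library, the correlation was 0.623 and the covariance 0.267 over 11603 genes. Of their genes past the rule, 178 were higher and 307 lower in both, against 24.4 and 25.1, and 7 went opposite ways. Past the rule in all 3 compounds were 162 higher and 297 lower genes.

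The 2 vehicle libraries were also compared with each other. They lie in separately normalized tables, so their difference includes any shift between tables. Comparisons inside 1 table do not carry such a shift, so the count between vehicles is no direct background for those of the compounds. Of 11572 genes, 168 were higher and 123 lower in vehicle 2 than in vehicle 1, or 2.51%. The corresponding share was 14.7% for YDGY-3, 21.8% for YDGY-3BR and 6.45% for IPZ. The androgen-induced list differed between the vehicles by a median of 0.34 and DNA repair genes by 0.43, and 2 of 32 and 1 of 31 members passed the rule, all higher in vehicle 2. For fatty acid synthesis genes the median was 0.39 (percentile 100) with 0 of 17 past the rule. Medians were also higher in vehicle 2 for ER chaperone (0.29, percentile 99.97), nucleoporin (0.29, percentile 99.83), importin (0.24, percentile 99.86) and G2/M genes (0.23, percentile 99.98). They were lower for AP-1 (-0.08, percentile 0.87) and histone genes (-0.11, percentile 2.14). These 9 lists were those outside the central 95% of matched random lists, and the cholesterol list, at 0.00, was not among them. As these percentiles arose with no compound in either library, a percentile near 0 or 100 for a compound does not by itself mark an effect of that compound.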

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

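The tests of the cholesterol list against vehicle 1 and of library scaling were chosen only after the result was seen. Fatty acid synthesis genes stood apart from matched random lists in opposite directions in the treated libraries. Their median difference was 0.64 with IPZ (percentile 100), -0.50 with YDGY-3 (percentile 0.29) and -0.79 with YDGY-3BR (percentile 0.03). FASN, the fatty acid synthase gene, differed by 0.98, -1.08 and -1.19, and SCD, a desaturase gene, by 1.83, -0.82 and -0.80. The difference between compounds was not tested, because each has 1 library. The list's median was also 0.39 higher in vehicle 2 than in vehicle 1.

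Cholesterol biosynthesis genes were higher with IPZ, with 19 of 25 past the size rule. A low level of these genes in vehicle 2 was argued against, since against vehicle 1 the list's median was 1.56. For library scaling, the median difference over genes with a mean FPKM of at least 5 was -0.018 with IPZ. A scale factor raises every gene alike, so a common upward offset left in these values was argued against. FPKM is already scaled by depth, which keeps that median small, so the test was weak. A response of the cells to IPZ may account for the pattern, as a hypothesis found and tested on the same data. A difference between the IPZ culture and the vehicle cultures stays open as well, because IPZ has 1 library.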

How the results depend on the processing

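The TMM scaling was added after the data were seen, and all 6 counts it was run on stayed within 1.5 times. Which side held more genes past the size rule depended on the setting. For YDGY-3BR, lower genes were more numerous (1297 higher, 1352 lower), but higher genes were with centred differences (1518, 1044), TMM (1429, 1157), vehicle 1 (1758, 1602) and a size rule of 2. For IPZ (365, 401), higher genes were more numerous with centred differences (386, 384), a pseudocount of 0.1 (611, 557), vehicle 1 and a size rule of 2. For IPZ against YDGY-3BR (819, 938), they were with a pseudocount of 0.1 (1263, 1174). With centred differences the small medians of the hypoxia and Wnt lists for YDGY-3BR changed sign. A size rule of 2 gave, by its own construction, fewer genes: 243 higher and 99 lower for YDGY-3, 388 and 182 for YDGY-3BR, 53 and 42 for IPZ, 88 and 263 for IPZ against YDGY-3BR, 285 in both YDGY compounds and 38 between the vehicles. A pseudocount of 0.1 gave 611 genes higher with IPZ, 1263 higher with IPZ than with YDGY-3BR, 624 between the vehicles and a correlation of 0.912 for the YDGY compounds. Against vehicle 1, IPZ had 927 genes higher and 724 lower. The correlation of the YDGY compounds was 0.900 with no filter and 0.932 with an FPKM of at least 5. That of IPZ and YDGY-3BR was 0.590 with an FPKM of at least 5 and 0.423 without a shared control. The cause of these changes, other than under the size rule of 2, was not tested. The other counts stayed within 1.5 times under each setting run. Removing the filter on low values could not change a count. With a pseudocount of 1, a gene below 1 FPKM in both libraries cannot differ by 1. Of 88 list medians outside the central 95% of matched lists drawn anew (the ribosomal list for YDGY-3BR, at percentile 2.78 in the first draw, was among them), 86 stayed on the same side with a pseudocount of 0.1 and 88 with centred differences. Centring shifts a list and its matched random lists alike, so apart from the random draws it could not move a percentile and is no check of the lists. Of the 88 medians, 7 grew over 1.5 times with the pseudocount of 0.1. For YDGY-3 they were 2.18 (interferon), 4.10 (basal) and 3.09 (leukocyte), against 1.33, 1.70 and 1.28, and for YDGY-3BR 3.48 (basal) against 1.65. For IPZ against YDGY-3BR they were -3.80 (basal), -1.26 (mesenchymal) and -2.99 (endothelial and erythroid), against -1.80, -0.66 and -1.84. With centred differences the ribosomal median for YDGY-3BR was -0.25 against -0.38. No paired analysis was possible because each treated group has 1 library, and for the same reason no library could be left out. Depth limits low genes: below 10 reads in a library, counting error alone spans a wide ratio, as for MMP12.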

Other observations

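The leukocyte, library scaling and separate-experiment tests in this part were chosen only after the result was seen. Apoptosis regulators were higher in 6 of 30 cases with YDGY-3, 9 of 30 with YDGY-3BR and 3 of 30 with IPZ, and lower in 1, 2 and 2. The BH3-only genes BIK (2.84 with YDGY-3BR) and BBC3 (3.12) were among them, and BIRC5, the survivin gene, was lower (-2.33). Autophagy and lysosome genes were higher in 9, 12 and 7 of 28 cases and lower in 0, at percentile 100 in each, led by SQSTM1 and NEU1 (2.94 with YDGY-3BR and 2.05 with IPZ). Among p53 targets 6, 6 and 7 of 31 were higher and 1, 2 and 0 lower, with CDKN1A, the cell cycle inhibitor p21, at 2.57, 3.63 and 1.81. Basal epithelial markers were higher in 5 of 9 cases with YDGY-3, 6 of 9 with YDGY-3BR and 0 of 5 with IPZ, and 1 was lower in each. The list had 13 members listed for YDGY-3 and 14 for each other compound. Those below 1 FPKM in both libraries were not counted, so these shares are not directly comparable. LAMB3 differed by 4.03 and 4.70 with the YDGY compounds. Mesenchymal genes were higher in 5 of 10, 4 of 11 and 1 of 8 cases, with ACTA2 at 4.47 and 3.79 with the YDGY compounds, and lower in 1, 0 and 0. Luminal identity genes split, with CLDN4 at 3.29 and 4.32 and CLDN3 at 2.94 and 3.59 with the YDGY compounds. They were higher in 5 of 21, 5 of 20 and 3 of 21 cases and lower in 3, 5 and 2.

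Replication-dependent histone genes were higher in 5 of 18, 7 of 16 and 1 of 15 cases with YDGY-3, YDGY-3BR and IPZ, and lower in 1, 1 and 0. Their transcripts are largely without poly(A) tails, so these values rest on a minor form. In the heat shock list CRYAB and HSPB8 (4.47 and 5.80 with the YDGY compounds) were far higher, and 3 of 23, 3 of 22 and 1 of 22 members were higher and 1, 3 and 0 lower. Unfolded protein response genes were higher in 1 of 28, 3 of 29 and 3 of 29 cases and lower in 1, 2 and 1, with ERO1A at 2.10 and 3.15 with the YDGY compounds. Oxidative phosphorylation genes were lower in 1, 4 and 0 of 48 cases, and cytosolic ribosomal protein genes and proteasome genes in 0 of 55 and 0 of 31 with any compound. Hypoxia and glycolysis genes were higher in 3, 5 and 1 of 30 cases and lower in 2, 3 and 3, with EGLN3 at 2.39 with YDGY-3. Androgen-repressed genes were higher in 2 of 10, 4 of 13 and 1 of 11 and lower in 3, 5 and 0, with CAMK2N1 at 1.89 with YDGY-3 and DDC at -3.01 with YDGY-3BR. Wnt targets were higher in 1 of 11, 1 of 10 and 1 of 9 cases and lower in 1, 2 and 1. Neuroendocrine genes were higher in 1 of 5, 1 of 5 and 0 of 6 cases and lower in 1, 2 and 0, with ENO2 at 2.08 and 2.16 with the YDGY compounds. Endothelial and erythroid markers reached 1 FPKM in 1, 3 and 2 cases, all of them the globin genes HBA1, HBA2 and HBB. With YDGY-3BR 2 of the 3 were higher (HBA2 and HBB) and 1 lower (HBA1), for a median of 1.29, and with the other compounds 0 passed the rule. HBA1 and HBA2 are near-identical copies and stay uncertain.

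NF-kB, AP-1 and interferon genes were higher in both YDGY libraries. Leukocyte RNA is argued against, since of 8 abundant leukocyte genes the 7 found in the tables reached at most 4.54 FPKM (ITGAM) in these libraries, where the test needed 50; CD68, which other cells also express, was not among the 8. For library scaling, the median difference over genes with a mean FPKM of at least 5 was -0.009 with YDGY-3 and -0.129 with YDGY-3BR. A scale factor raises every gene alike, so a common upward offset left in these values is argued against. Because FPKM is already scaled by depth, that median is kept small and the test is weak. A response of protein kinase C type is a candidate explanation: in a list of phorbol ester induced genes fixed before its test, without members of those 3 lists, 12 of 16 and 12 of 19 genes were higher with YDGY-3 and YDGY-3BR (percentile 100 in each), with TNFRSF12A at 2.38 and 3.03. With IPZ the same list had 2 of 10 higher (percentile 30.5). Of its 28 members, only those reaching 1 FPKM in the higher library were counted, so the shares are not directly comparable between compounds. Kinase activity itself was not measured, so other inducers of these genes stay open.

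Differences were larger with YDGY-3BR than with YDGY-3, with a principal-axis slope of 1.25. With the vehicles exchanged the slope was 1.59. The exchange adds the difference between vehicles to the 2 compounds with opposite signs, which by itself can push such a slope further from 1. It therefore does not decide whether the choice of vehicle is the source of a slope above 1. The size of the slope did depend on the vehicle, and the exchange sets values across separately normalized tables. Low genes and the pseudocount are argued against, since the slope was 1.21 among 4175 genes with a mean FPKM of at least 20. Whether the compounds or their separate experiments made the difference cannot be told apart, because they lie in separate tables, and 2.51% of genes passed the rule between the vehicles. A stronger response to YDGY-3BR at this dose may explain it, as a hypothesis that a repeat with both compounds in 1 experiment would test.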
